A study of Mus musculus with 10 samples.

How the data were processed

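Gene expression was measured on 10 arrays, each from 1 sorted population of mouse embryonic stem cells with doxycycline-inducible Meis2 after co-culture on OP9-GFP stroma. The labels state extraction with RNeasy kits and NuGEN amplification from 50 ng total RNA. The values are RMA values by the authors, and the deposited values are in log2: RMA is named in the submitters' processing notes with no version or settings, and the log2 scale was inferred from the values. RMA corrects background, normalizes between arrays and summarizes the probes of a transcript. No value was missing, and the values were used as deposited. Depth does not apply to arrays; their number limits the precision.

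Of 29674 probes, 21780 had 1 gene symbol in the platform's probe table, 1618 had several and 6276 were not listed. Of the probes with 1 symbol 21689 matched a RefSeq gene by Entrez identifier, and no symbol was changed by this. The 21780 probes stood for 19933 genes, and for the 996 genes with more than 1 probe the probe with the highest mean was used. The genes in the lowest 0.25 by mean (below 1.938) were left out, which left 14949 genes. The files hold no detection calls, so no background level is known, and a difference from a group with both arrays below 1.938 is read as at best a lower bound.

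Tests used limma 3.58.1 and statmod 1.5.0 in R 4.3.3. The model held a term for each of the 5 combinations of day and population and a term for doxycycline, with 4 residual degrees of freedom and 6.12 prior degrees of freedom. Contrasts of populations came from the same fit, 2 arrays against 2. A doxycycline term for CD41-expressing populations, or for day 8, tested whether the response differed. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, two-sided. Swapping the signs of 5 pairs gives 16 arrangements, so an exact sign-flip test of a single gene cannot go below p = 0.0625. Simulated changes in 50 genes of each size were recovered in 32% at 0.5 log2 units, 94% at 1, 98% at 2 and 100% at 4 for doxycycline, with 5 false calls, in 4%, 52%, 92% and 100% for a contrast of populations, with 11 false calls, and in 0%, 14%, 92% and 100% for the CD41 interaction, with 7. Each simulated doxycycline change was the same in all 5 pairs, with independent noise. All sizes were changed together, which eases the adjusted threshold. The shares therefore do not hold for responses that differ between populations or for data with few changed genes.

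There were 22 gene lists: erythroid, megakaryocyte, haematopoietic progenitor, endothelial, myeloid, mast cell and basophil, stromal and mesenchymal, cardiac muscle, pluripotency, endoderm and epithelium, neural, Meis with Pbx and Hox, cell cycle, Hoxa9 and Meis1 leukaemia genes, p53 targets, integrated stress response, mitochondrially encoded, interferon response, retinoic acid response, early response, cholesterol synthesis, and hypoxia and glycolysis. Some genes are on more than 1 list (Cd34, Lmo2 and Meis1, for example). Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were the alternatives. Counts of members are over all genes tested unless given as adjusted over the list alone. Within a single pair, the median of a list was placed among 10000 random lists of the same size matched on mean level. Random lists do not carry the correlation between members, so a list whose members move together reaches extreme percentiles more easily. In the doxycycline comparison the estimated correlation was 0.17 for the erythroid list, and 0.24 for the endothelial and pluripotency lists. Short lists of housekeeping and purine genes were written later, for the closing tests.

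The comparisons, the lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, for doxycycline, the Meis and Pbx family and the 10 largest rises and falls past the threshold, filled with genes moving alike in all 5 pairs and named as not passing. For each contrast of populations it takes Itga2b, Ptprc and the 8 largest each way; for a list up to 4 members with the largest effect; for an interaction the 5 largest each way past the threshold or the 3 smallest p; for a single population Meis2 and the 3 largest differences each way among genes above the median level.

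Alternatives were no filter, a filter on the lower 50% of genes, a further quantile normalization, the mean of a gene's probes, trended robust variances, array weights, an adjusted threshold of 0.1, leaving out each pair or array, a mean per treatment and day, no block of populations, CD41-expressing or CD41- populations alone, and the other set tests. A test of all probes with at least the same mean, 16390 with 1 symbol, 1171 with several and 4187 with none, was chosen after seeing the data. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.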

Results

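Mouse embryonic stem cells carrying a doxycycline-inducible copy of Meis2 (the A2lox.Meis2 line) were grown as embryoid bodies for 6 days, dissociated, and plated with blood-promoting cytokines on irradiated OP9-GFP cells. OP9 is a stromal line commonly used to support blood formation, here marked with green fluorescent protein. Meis2 encodes a TALE-class homeodomain transcription factor that binds DNA together with Pbx and Hox proteins. Doxycycline was added on day 6 at 500 ng/ml or left out. Cells without green fluorescence were sorted by their surface level of CD41, the integrin subunit encoded by Itga2b that marks early blood progenitors and megakaryocytes. On day 7, after 24 hours of doxycycline, CD41- and CD41+ cells were collected. On day 8, after 48 hours, CD41-, CD41int (intermediate) and CD41hi cells were collected. Each of the 10 combinations of day, population and treatment was measured on 1 array, which gave 5 untreated and 5 doxycycline arrays, or 5 pairs. Median log2 values of the arrays lay between 2.61 and 2.71 over all probes, and Pearson correlations between arrays over the 14949 genes tested lay between 0.935 and 0.989. The number of arrays limits the precision of every value, and no combination had a replicate. The p-values take their error from how far the doxycycline-minus-untreated differences of the 5 pairs disagree, in contrasts of populations too. The labels do not say whether the populations of a day came from the same co-culture, so the p-values are too small as tests over independent cultures.

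The series was set up to find genes that respond to Meis2, and the first comparison was doxycycline against no doxycycline over the 5 populations. Meis2 itself (probe 10486041) rose with doxycycline, by 2.64 on the log2 scale or 6.25-fold (SD 1.04, n = 5 pairs; limma adjusted p = 0.0445). Its difference was largest in day 8 CD41hi cells (3.71) and day 7 CD41+ cells (3.66), and smallest in day 8 CD41- cells (1.46). Hprt (probe 10599627), the X-linked gene of a purine salvage enzyme, was the other gene that passed, and it rose 2.21-fold (log2 1.14, SD 0.288, n = 5 pairs; limma adjusted p = 0.0445). Its difference lay between 0.75 and 1.49 in the 5 pairs. No gene fell past the threshold in limma. At an unadjusted p under 0.05 there were 899 genes, 483 of them lower with doxycycline, where 747.5 were expected by chance. Genes higher in all 5 pairs numbered 478 (3.20% of genes) and genes lower in all 5 numbered 592 (3.96%), where chance gives 467.2 (3.125%) in each direction.

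**Figure D1:**
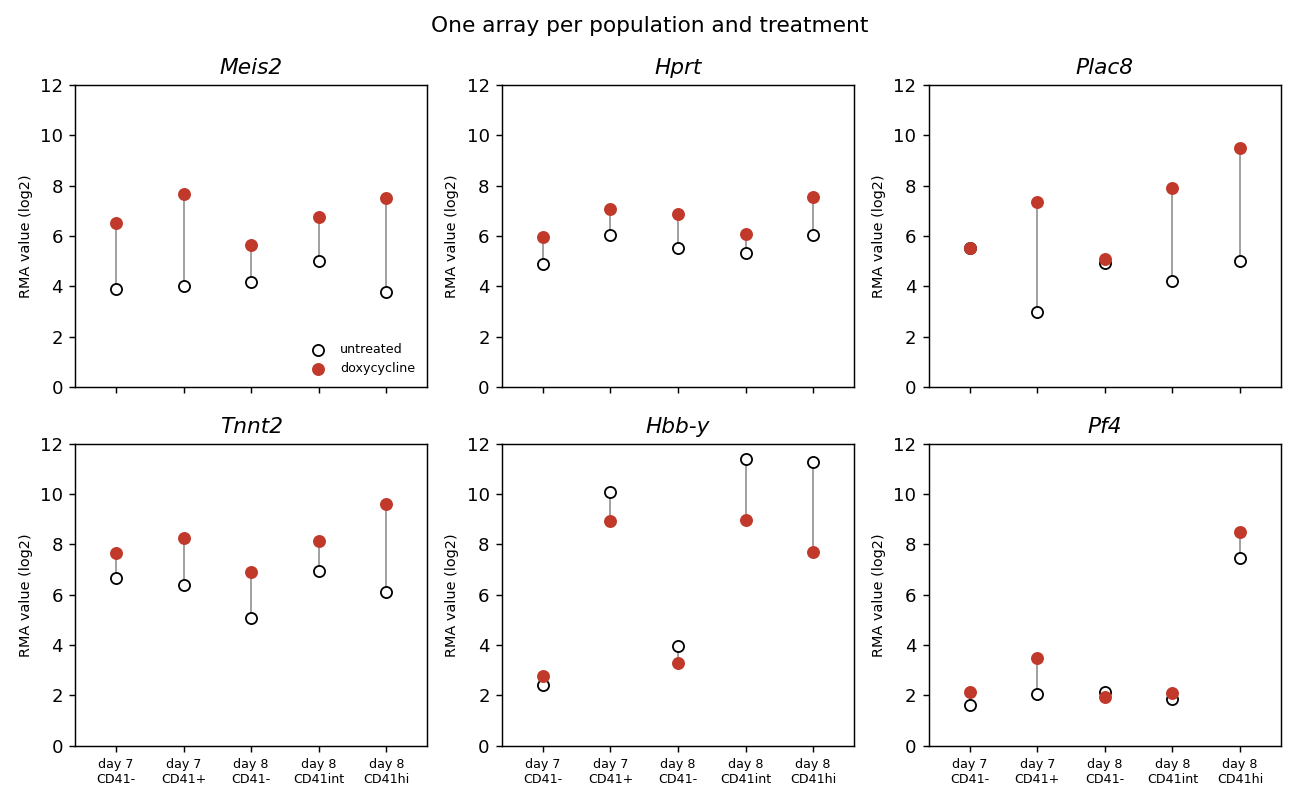
RMA values (log2, vertical axis) of 6 genes on each of the 10 arrays, with populations on the horizontal axis, untreated arrays as open circles, doxycycline arrays as filled circles and a line joining the arrays of a pair. Meis2 and Hprt were higher with doxycycline in all 5 pairs, Plac8 rose from 2.97 to 7.37 in day 7 CD41+ cells while it was 5.50 and 5.53 in day 7 CD41- cells, and Hbb-y was lower in day 8 CD41hi cells, at 7.69 against 11.29.

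The count of 2 genes was sensitive to single pairs. It was 0 without the day 7 CD41- pair, the day 7 CD41+ pair, the day 8 CD41int pair or the day 8 CD41hi pair, and 1 without the day 8 CD41- pair, when Meis2 kept its call (adjusted p = 0.0453) and Hprt lost it (0.242). It was 1, Hprt, when the lower 50% of genes by level was left out or the arrays were quantile-normalized again, and 0 without the block of populations. Over all probes of the array, a test chosen after seeing the data, it was 0 as well. With a mean per treatment and day Meis2 kept its call (limma adjusted p = 0.0165) and Hprt lost it (0.095). Such means hide disagreement between the populations of a day and leave fewer residual degrees of freedom. Plac8 passed there as well (limma adjusted p = 0.0131), although it differed by 0.03 in day 7 CD41- and 4.40 in day 7 CD41+ cells. The partners and relatives of Meis2 were not called. Meis1, Meis3, Pbx2, Pbx3 and Pbx4 differed by 0.08, 0.10, 0.21, 0.02 and -0.09 on the log2 scale, each with an adjusted p of at least 0.858. The sign turned without a single pair for Meis1 (-0.03 without day 7 CD41+), Pbx3 (-0.09 without day 7 CD41-) and Pbx4 (0.03 without day 8 CD41hi). Of the 33 tested genes of the Meis, Pbx and Hox list, 1 (Meis2) rose over all genes tested and 2 adjusted over the list alone, the second being Hoxa5 at 0.46 (SE 0.10). The list as a group did not pass (camera adjusted p = 0.0946), and it passed without the block of populations (adjusted p = 0.0364). It holds Meis2, the gene that doxycycline was used to induce, so part of its rise was set by the design. The list was not tested without Meis2, so neither value speaks for the partners and relatives. Its median was 0.05 on the log2 scale.

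Genes of embryonic red cells were lower with doxycycline. The erythroid list had a median of -0.27 on the log2 scale, with 24 of its 25 tested members lower. It passed the preset-correlation set test (camera adjusted p = 5.51e-11). The call was lost with an estimated correlation (adjusted p = 0.282 with an estimated correlation), and fry gave an adjusted p of 0.228. Adjusted over the list alone 8 members fell, and over all genes tested none did. The 8 included the embryonic globins Hbb-y (-1.49, SE 0.44), Hba-x (-1.45, SE 0.37) and Hbb-bh1 (-0.89, SE 0.23), and Slc25a37 (-0.92, SE 0.24), the mitochondrial iron importer used in haem synthesis. Klf1 and Gata1, transcription factors of the lineage that were picked after their values were seen, were at -0.40 (SE 0.18) and -0.20 (SE 0.15) and did not pass. Adult globins are measured by probes shared between near-identical genes, so they cannot be assigned to a single gene. The 2 probes of the Hba-a1 and Hba-a2 pair were at -1.79 and -1.81, and those of the adult Hbb genes at -0.67 and -0.90, with adjusted p of at least 0.776.

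Genes of heart muscle tended the other way, by a small amount. Retinoic acid response and pluripotency lists, which did not pass, had medians of like size (0.10 each). The cardiac muscle list had a median of 0.12 on the log2 scale, and 18 of 23 tested members were higher. It passed with the preset correlation (camera adjusted p = 0.000273) but not with the other set tests (adjusted p = 0.282 with an estimated correlation; fry adjusted p = 0.140). Adjusted over the list alone 4 members rose and over all genes tested none: Tnnt2, cardiac troponin T (1.88, SE 0.29), Actc1, cardiac alpha-actin (0.64, SE 0.14), Myl4, the atrial light chain of myosin (0.55, SE 0.13), and Csrp3 (0.36, SE 0.11). Nkx2-5 and Hand1, transcription factors of the early heart, were at -0.15 and -0.24 and did not pass; these and Csrp3 were picked after their values were seen. Tnnt2 was higher in all 5 pairs, from 0.98 in day 7 CD41- cells to 3.49 in day 8 CD41hi cells, yet its adjusted p over all genes was 0.342.

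None of the remaining 19 lists passed. Megakaryocyte genes had a median of 0.00 (camera adjusted p = 0.979). Adjusted over that list alone 2 of its 26 members fell, Nfe2 (-0.78, SE 0.13), a transcription factor of platelet and red cell maturation, and F2rl3 (-0.77, SE 0.20), a thrombin receptor. Pf4, platelet factor 4, was at 0.60 (SE 0.20) and did not pass. Haematopoietic progenitor genes had a median of -0.04 (camera adjusted p = 0.943, with the test pointing up) and 1 of 37 rose adjusted over the list alone, Lmo2 (0.63, SE 0.14). Lmo2 was also the 1 gene of the 23 on the list of Hoxa9 and Meis1 leukaemia genes that rose in that sense, and that list had a median of -0.04 with the test pointing up (camera adjusted p = 0.917). In the stromal and mesenchymal list (median 0.05, camera adjusted p = 0.306) Twist1 rose (0.56, SE 0.10) and Postn fell (-0.72, SE 0.13), both adjusted over the list alone. Markers of other cells a sort could hold had medians near 0 over the 5 pairs, although single pairs went opposite ways. Endothelial medians were -0.45 in day 8 CD41hi and 0.19 in day 8 CD41int cells, pluripotency medians -0.1956 in day 7 CD41- and 0.36 in day 8 CD41int cells, and the myeloid median -0.29 in day 8 CD41int cells. Over all pairs the medians of the endothelial, myeloid, mast cell, endoderm, neural and pluripotency lists were -0.04, -0.04, -0.04, 0.01, -0.05 and 0.10. Their camera adjusted p were 0.694, 0.354, 0.433, 0.433, 0.318 and 0.282, and the pluripotency list passed without the day 7 CD41+ pair (0.0293). Lists of stress and growth had medians near 0 over the 5 pairs as well. In single pairs the early response list was at -0.2158 in day 8 CD41hi cells (percentile 1.69) and the integrated stress response at -0.1381 in day 8 CD41int cells (percentile 0.87), the pairs with the lowest erythroid medians. Over all pairs medians were -0.03 for the integrated stress response, -0.04 for p53 targets, -0.05 for early response genes, -0.05 for hypoxia and glycolysis and -0.04 for the interferon response. They were 0.04 for the cell cycle, 0.05 for cholesterol synthesis and 0.10 for the retinoic acid response. Their adjusted p lay between 0.184 and 0.369. Only 2 mitochondrially encoded genes were measured (median 0.06, camera adjusted p = 0.503).

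Among genes that moved the same way in all 5 pairs without passing the test, the largest mean rises after Tnnt2 and Plac8 were those of the imprinted RNA Rian (0.78), the calcium sensor Vsnl1 (0.73), the small RNA host DQ267102 (0.71), the phospholipase Plaat3 (0.71), the transcription factor Nfil3 (0.70) and Actc1. Besides globins, Slc25a37, Nfe2 and F2rl3, the largest mean falls were those of the myeloid receptor Igsf6 (-0.83), Tfec (-0.88), a transcription factor of the Mitf family, Car2 (-0.86), red cell carbonic anhydrase, and Ccn3 (-0.79). Their adjusted p lay between 0.342 and 0.786. Clec4n, a myeloid receptor, was also lower in all 5 pairs, but it lay below the filter value of 1.938 on 8 of the 10 arrays, so no size is given for it. Nfe2 and Vsnl1 lay below that value on both day 8 CD41- arrays.

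**Figure D2:**
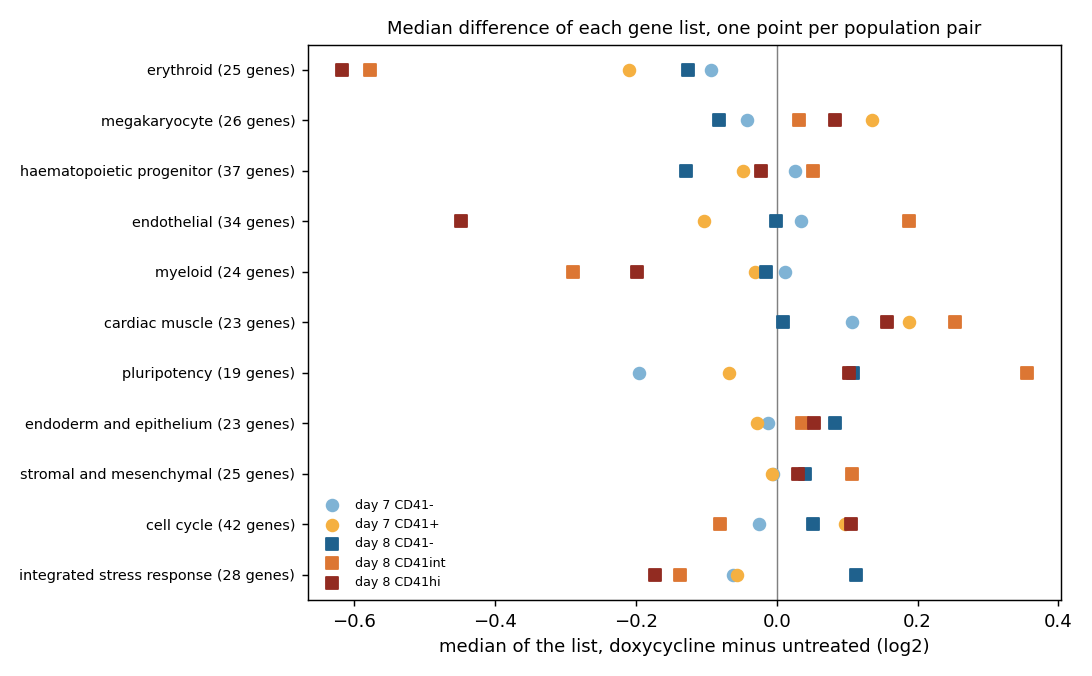
Median doxycycline-minus-untreated difference (log2, horizontal axis) of 11 gene lists, with a point for each of the 5 population pairs (circles day 7, squares day 8) and no error bars, since each pair is 2 arrays. The erythroid medians lie below 0 in all 5 pairs, at -0.62 in day 8 CD41hi and -0.58 in day 8 CD41int cells, and the endothelial median is -0.45 in CD41hi and 0.19 in CD41int cells of day 8.

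Within each population the difference between the 2 arrays has no replicate check, and the values that follow describe those arrays. Differences of at least 2-fold were seen for 120 genes in day 7 CD41- cells (59 higher), 114 in day 7 CD41+ cells (47 higher), 41 in day 8 CD41- cells (24 higher), 138 in day 8 CD41int cells (63 higher) and 250 in day 8 CD41hi cells (88 higher). Across genes, which are not independent replicates, the differences of 2 pairs correlated with r between -0.0332 and 0.142, the highest being day 7 CD41+ with day 8 CD41hi. Erythroid medians were -0.21, -0.58 and -0.62 in day 7 CD41+, day 8 CD41int and day 8 CD41hi cells, at percentiles 0.23, 0.00 and 0.00 of 10000 random lists of like size and level. They were -0.0932 and -0.1256 in CD41- cells of day 7 and day 8, at percentiles 10.76 and 1.17. In the day 8 CD41- pair the haematopoietic progenitor median was -0.1288 (percentile 0.35). Random lists lack the correlation between members, so percentiles overstate how unusual a list is when its members move together. The rankings of genes that follow are among tested genes above the median level, which leaves out the shared probes of adult globins. In day 8 CD41hi cells Hbb-y, Hba-x and Gimap6 were lowest (-3.60, -3.59 and -2.19), and Plac8, Meis2 and Armh4 highest (4.47, 3.71 and 3.60). The shared probes of Hba-a1 and Hba-a2 were lower still in these cells (-4.33 and -4.22). The endothelial median was -0.45 there (percentile 0.00) and 0.19 in day 8 CD41int cells (percentile 99.5). In CD41int cells Plac8, the fatty acid carrier Fabp4 and A530032D15Rik were highest (3.69, 2.97 and 1.91). Hbb-y, the chemokine Ccl9 and the myeloid adaptor Tyrobp were lowest there among the same genes (-2.41, -2.02 and -1.76), with the shared Hba-a1 and Hba-a2 probes at -2.66 and -2.70. Beside these falls the pluripotency median in CD41int cells was 0.36, with 18 of 19 members higher (percentile 100), and the myeloid median was -0.29 (percentile 0.07). In day 7 CD41+ cells Plac8, Meis2 and Stox2 were highest (4.40, 3.66 and 2.08). Pou5f1, Krt8 and A530032D15Rik were lowest there among the same genes (-1.62, -1.51 and -1.48), with the shared Hba-a1 and Hba-a2 probes at -1.75 and -1.79. Among CD41- cells, Meis2 (2.63), Dnajc30 (1.41) and Cacna2d1 (1.34) were highest and Mgst3 (-1.35), Ecscr (-1.33) and Ptpn1 (-1.29) lowest on day 7. On day 8 Tnnt2 (1.84), Meis2 (1.46) and Hprt (1.34) were highest and Ccdc173 (-1.19), Ddit4l (-1.16) and Gm266 (-1.13) lowest.

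Whether the response differed between CD41-expressing and CD41- cells was tested as an interaction. Plac8 (probe 10531724), a small cysteine-rich protein of myeloid and placental cells, was the 1 gene that passed: its response was larger in CD41-expressing cells by 4.09 on the log2 scale (SE 0.28; limma adjusted p = 0.00140). It was higher by 4.40, 3.69 and 4.47 in the 3 CD41-expressing pairs and by 0.03 and 0.17 in the 2 CD41- pairs. In a fit to the CD41-expressing pairs alone Plac8 was the 1 gene called, with an 18.2-fold rise (limma adjusted p = 0.000122). The erythroid list had a lower response in CD41-expressing cells, by a median of -0.54 (camera adjusted p = 3.89e-05), and this call was lost with the other set tests (adjusted p = 0.731 with an estimated correlation and 0.638 with fry). Its globin Hbb-bh1 had mean levels of 1.92 and 2.91 in CD41- cells of day 7 and day 8, against 10.33 in day 8 CD41hi cells, so a fall of it in CD41- cells had little room to show.

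The days held different populations, CD41- and CD41+ on day 7, and CD41-, CD41int and CD41hi on day 8. Day 8 cells also had doxycycline for longer. The test for day had no term for CD41 in the response, so effects of day and of population cannot be told apart. Between day 8 and day 7 no gene's response differed past the threshold in limma. At an unadjusted p under 0.05 there were 728 genes, where 747.5 were expected. The smallest p belonged to Myl9, Gbp4 and Olfr1510, whose responses differed by 1.56, -1.31 and -1.32 (adjusted p = 0.990 for each). Pluripotency genes responded more positively on day 8, by a median of 0.40 (camera adjusted p = 0.000125; adjusted p = 0.843 with an estimated correlation), and erythroid genes more negatively, by a median of -0.27 (camera adjusted p = 0.0300; adjusted p = 0.843 with an estimated correlation). Without the day 7 CD41- pair, the day 8 CD41int pair or the day 8 CD41hi pair the erythroid difference did not pass (adjusted p = 0.572, 0.3499 and 0.296).

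Sorted CD41+ cells of day 7 were higher than CD41- cells in genes of blood progenitors and megakaryocytes and lower in those of pluripotent cells and epithelium. Erythroid and endothelial lists were higher too, but their calls were lost with an estimated correlation (adjusted p = 0.0819 for each). Of the 14949 genes, 558 were higher and 599 lower in CD41+ cells, taking doxycycline and untreated arrays together with treatment as a term. The largest rises were those of the embryonic globins Hbb-bh1, at 8.82 on the log2 scale (SE 0.37, 2 arrays against 2), Hbb-y (6.90) and Hba-x (6.42), and of Ctla2a (5.52), Hapln1 (42.2-fold), Prkar2b (5.35), Calcrl (5.04) and Plek (4.96). The largest falls were those of the pluripotency gene Dppa5a (-5.31, SE 0.38), the keratin gene Krt8 (-4.99), Spink1 (-4.74), Tdgf1 (-4.73), Mt2 (-4.63), Zfp640 (-4.50), Apela (-4.48) and Dppa3 (-4.44), with adjusted p of at most 0.000190 for all 16. In CD41- cells Hbb-bh1 was at 1.941 and 1.900, close to the filter value of 1.938, so its difference is at best a lower bound and its rank is not settled. Itga2b, the gene of the sorting marker and so no finding, was 2.01-fold higher (adjusted p = 0.0477), and Ptprc, which encodes CD45, was at 0.66 and did not pass (adjusted p = 0.290). Itga2b did not pass without the untreated CD41-, doxycycline CD41- or doxycycline CD41+ array (adjusted p = 0.177, 0.2095 and 0.380), nor with no filter (0.0535) or quantile normalization again (0.0578). The number of calls fell to 585, 661, 666 and 524 when the untreated CD41-, untreated CD41+, doxycycline CD41- and doxycycline CD41+ array of day 7 was left out in turn.

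By list, 15 of 19 pluripotency genes fell and none rose in day 7 CD41+ cells (median -2.36, camera adjusted p = 3.14e-25). So did 9 of 23 endoderm and epithelium genes (median -0.44, adjusted p = 6.33e-10) and 6 of 19 neural genes (median -0.17, adjusted p = 4.12e-05), among them Sox2 (-3.62) and Stmn2 (-3.40). Progenitor genes rose, 13 of 37 (median 0.43, adjusted p = 4.96e-09), for example Cd93 (3.93), Cd34 (3.71), Hhex (2.36) and Myb (1.95). Megakaryocyte genes rose, 10 of 26, with 1 that fell (median 0.49, adjusted p = 1.35e-07), as did 9 of 23 leukaemia genes (median 0.31, adjusted p = 1.12e-05). These 6 calls held with an estimated correlation, at adjusted p between 0.0269 and 0.0341. The megakaryocyte list holds Itga2b, the gene of the sorting marker, so 1 of its 10 rises was set by the sort. Endothelial genes rose, 16 of 34 (median 0.95, adjusted p = 1.62e-14), among them Cdh5 (4.51), Ramp2 (3.63) and the VEGF receptor Kdr (3.57), and 8 of 25 erythroid genes rose (median 0.59, adjusted p = 1.95e-09). Both calls were lost in that test (adjusted p = 0.0819 with an estimated correlation for each). The same holds for cell cycle genes, 2 of 42 higher and 1 lower (median 0.17, adjusted p = 0.00451; 0.131 as adjusted p with an estimated correlation), and for cholesterol synthesis, 3 of 19 higher (median 0.21, adjusted p = 0.00937; 0.0819 as adjusted p with an estimated correlation). It holds too for stromal genes, 5 of 25 lower (median -0.12, adjusted p = 0.00451; 0.0819 as adjusted p with an estimated correlation). So it does for hypoxia and glycolysis, 4 of 27 lower and 1 higher (median -0.13, adjusted p = 0.0106; 0.0825 as adjusted p with an estimated correlation), and cardiac muscle, 5 of 23 lower and 2 higher (median -0.11, adjusted p = 0.0275; 0.147 as adjusted p with an estimated correlation), where Actc1 was at -3.16 and Mef2c at 2.39. The cardiac call was also lost without the untreated CD41- or the doxycycline CD41+ array (adjusted p = 0.0773 and 0.0562) and with no filter on dim genes (0.0756).

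On day 8 the same contrast, CD41hi against CD41-, gave 760 genes higher and 996 lower. Hbb-bh1 (7.42, SE 0.37), Ctla2a (6.85), Plek (6.66), Pf4 (5.95), Hbb-y (5.86), Prkar2b (5.43), Rgs18 (5.43) and Lilr4b (5.41) rose most. Dppa5a (-7.06, SE 0.38), Apela (-6.11), Tdgf1 (-5.37), Fbxo15 (-5.17), L1td1 (-5.05), Mt2 (-5.05), Pou5f1 (-5.04), which encodes Oct4, and Spink1 (-4.99) fell most, with adjusted p of at most 0.000349 for all 16. Itga2b was 2.81-fold higher (adjusted p = 0.00457) and Ptprc rose (adjusted p = 0.0126). In CD41- cells Ptprc was at 1.720 and 1.550, below the filter value of 1.938, so its 2.82-fold is at best a lower bound. The days were measured on separate arrays, and 787 genes were called on both days, 785 of them in the same direction. Independent lists would share 68.3. The 2 contrasts came from the same fit with a shared estimate of each gene's spread, so their lists were not independent and 68.3 is no chance level for them. Across genes the log2 differences of the 2 days correlated with r = 0.737. Ptprc did not pass without the untreated CD41-, untreated CD41hi or doxycycline CD41- array (adjusted p = 0.113, 0.0832 and 0.0623), and Itga2b not without the last of these (0.0588). The number of calls fell to 918, 939 and 1163 without the untreated CD41-, the doxycycline CD41- and the doxycycline CD41hi array of day 8.

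Megakaryocyte genes rose in day 8 CD41hi cells, 18 of 26 and none lower (median 1.38, camera adjusted p = 3.68e-21). So did 11 of 24 myeloid genes (median 0.66, adjusted p = 1.16e-08), with Tyrobp at 4.51 and the cytokine receptor Csf2rb at 3.89. Among the 18 megakaryocyte genes is Itga2b, the gene of the sorting marker, so that rise was set by the sort. The megakaryocyte list was not tested without Itga2b. Progenitor genes rose, 15 of 37 with 2 lower (median 0.53, adjusted p = 1.96e-08), with Lmo2 at 2.68 and Runx1 at 2.10, as did 5 of 19 cholesterol synthesis genes (median 0.37, adjusted p = 0.000105). Pluripotency genes fell, 17 of 19 (median -2.87, adjusted p = 3.61e-22), as did 12 of 23 endoderm and epithelium genes (median -0.92, adjusted p = 7.00e-09). These 6 calls held with an estimated correlation, at adjusted p between 0.00901 and 0.0458. Erythroid genes rose, 10 of 25 (median 0.70, adjusted p = 7.00e-09; adjusted p = 0.0794 with an estimated correlation), and endothelial genes, 10 of 34 with 2 lower (median 0.47, adjusted p = 5.50e-07; adjusted p = 0.176 with an estimated correlation). Leukaemia genes rose, 7 of 23 (median 0.23, adjusted p = 0.000943; adjusted p = 0.0525 with an estimated correlation). Interferon response genes rose, 5 of 23 (median 0.14, adjusted p = 0.00549; adjusted p = 0.162 with an estimated correlation), as did mast cell genes, 1 of 6 (median 0.31, adjusted p = 0.0308; adjusted p = 0.162 with an estimated correlation), that gene being Cpa3, which lay below the filter value on both CD41- arrays, so that its 1.66 is at best a lower bound. The interferon call was lost without the untreated CD41hi array (adjusted p = 0.0865), and the mast cell call without the doxycycline CD41- or doxycycline CD41hi array (0.0789 and 0.0649) or with quantile normalization again (0.0526). Neural genes fell, 6 of 19 (median -0.18, adjusted p = 0.00103; adjusted p = 0.0525 with an estimated correlation), as did stromal genes, 5 of 25 (median -0.07, adjusted p = 0.00838; adjusted p = 0.0775 with an estimated correlation). Hypoxia and glycolysis genes fell, 7 of 27 with 1 higher (median -0.23, adjusted p = 0.00134; adjusted p = 0.0529 with an estimated correlation), led by the collagen prolyl hydroxylases P4ha2 (-2.84) and P4ha1 (-2.70).

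**Figure D3:**
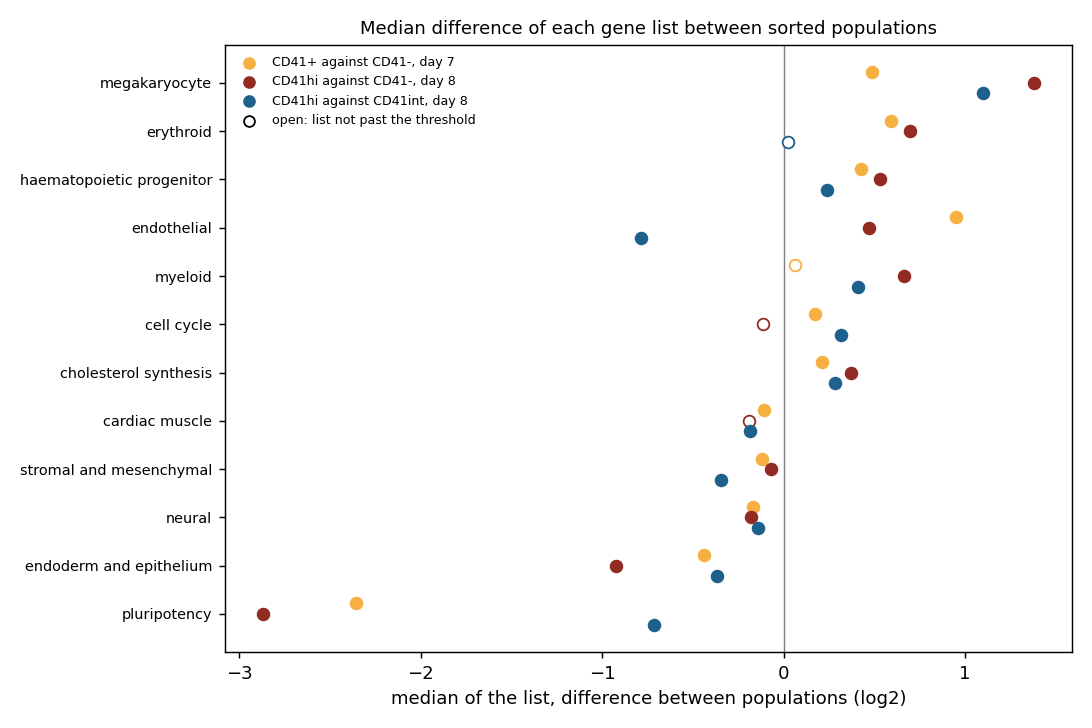
Median log2 difference (horizontal axis) of 12 gene lists in 3 comparisons of sorted populations, each from 2 arrays against 2; filled points passed the set test with a preset correlation and open points did not. The endothelial list lies at 0.47 in CD41hi against CD41- cells of day 8 and at -0.79 in CD41hi against CD41int cells, and the erythroid list is at 0.02 in the latter.

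Within the CD41-expressing cells of day 8, CD41hi cells were higher in megakaryocyte genes, and CD41int cells in endoderm, epithelium and stromal genes. CD41hi cells had 334 genes higher and 441 lower than CD41int cells. Pf4 (6.00, SE 0.32), the thrombin receptor F2rl2 (5.08), Rgs18 (4.55), Plek (4.15), the platelet glycoprotein Gp5 (3.35), Cd226 (3.21), Sla (3.19) and Lilrb4a (3.06) rose most. Dppa5a (-4.03, SE 0.38), Apela (-3.62), Klhl4 (-3.59), Spink1 (-3.43), Nexn (-3.11), Peg3 (-2.88), Mme (-2.82) and Actc1 (-2.79) fell most, with adjusted p of at most 0.00205 for all 16. Cd226 lay below the filter value on both CD41int arrays, so its difference is at best a lower bound. Itga2b was at 0.94 (adjusted p = 0.0784) and Ptprc at 0.74 (adjusted p = 0.257), and neither passed; Itga2b passed without the untreated CD41int array (1.33) and with trended robust variances (adjusted p = 0.0452), and Ptprc without the doxycycline CD41hi array (1.39). The number of calls fell to 445, 296 and 412 without the untreated CD41int, the doxycycline CD41int and the doxycycline CD41hi array.

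Of 26 megakaryocyte genes 15 rose in CD41hi over CD41int cells and none fell (median 1.10, camera adjusted p = 4.02e-21). Of the other groups, 9 of 23 endoderm and epithelium genes (median -0.37, adjusted p = 3.85e-08) and 5 of 25 stromal genes fell (median -0.35, adjusted p = 3.30e-08), among them Postn (-2.73) and the smooth muscle actin gene Acta2 (-2.64). These 3 calls held with an estimated correlation, at adjusted p of 0.00879, 0.0230 and 0.0230. Endothelial genes fell, 11 of 34 (median -0.79, adjusted p = 5.37e-14), for example Emcn (-2.78) and Cdh5 (-2.55). Pluripotency genes fell, 7 of 19 (median -0.71, adjusted p = 5.32e-10), and both calls were lost in that test (adjusted p = 0.106 with an estimated correlation for each). Cell cycle genes rose, 4 of 42 (median 0.32, adjusted p = 1.52e-07; adjusted p = 0.0687 with an estimated correlation), among them Foxm1 (0.82) and Mki67 (0.66). Myeloid genes rose, 6 of 24 (median 0.41, adjusted p = 0.000191; adjusted p = 0.106 with an estimated correlation), as did progenitor genes, 7 of 37 with 3 lower (median 0.24, adjusted p = 0.0137; adjusted p = 0.106 with an estimated correlation), where Runx1 was at 1.97 and Cd93 at -2.42. Cholesterol synthesis genes rose, 2 of 19 (median 0.28, adjusted p = 0.0138; adjusted p = 0.106 with an estimated correlation). Interferon response genes fell, 6 of 23 (median -0.51, adjusted p = 1.25e-06; adjusted p = 0.0913 with an estimated correlation), with Rsad2 at -1.66 and Ifit3 at -1.61. Cardiac muscle genes fell, 4 of 23 with 1 higher (median -0.18, adjusted p = 0.0219; adjusted p = 0.127 with an estimated correlation), as neural genes did, 2 of 19 (median -0.14, adjusted p = 0.0223; adjusted p = 0.106 with an estimated correlation). The retinoic acid response list pointed down (median -0.37, camera adjusted p = 0.0300, and 0.118 as adjusted p with an estimated correlation). Of its 15 genes 11 were lower, but only 1 fell and 1 rose past the threshold. The cardiac call was lost without the untreated CD41hi or doxycycline CD41int array (adjusted p = 0.221 and 0.0829) and with no filter on dim genes (0.0535). Cholesterol and neural calls were lost without the untreated CD41int (0.0582 and 0.0715) or untreated CD41hi array (0.0528 and 0.161), and with the lower 50% of genes left out (0.0528 and 0.0859). The retinoic acid call was lost without the untreated CD41int, untreated CD41hi or doxycycline CD41hi array (0.0546, 0.1001 and 0.0727). Erythroid genes did not pass (median 0.02, camera adjusted p = 0.873). Meis1 was higher in day 7 CD41+ than in CD41- cells, by 1.01 on the log2 scale (limma adjusted p = 0.0156). In day 8 CD41hi cells it was higher than in CD41- cells by 1.14 and than in CD41int cells by 1.03 (limma adjusted p = 0.00566 and 0.0202). These last comparisons share the CD41hi arrays. CD41int was not tested against CD41- cells, and the like size of the differences shows no graded rise of Meis1 with CD41 on day 8.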

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

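The tests of explanations for the erythroid and Plac8 patterns in this part were chosen only after the result was seen, and some of them replaced or joined earlier ones whose results were known. The tests of the differences themselves with their alternatives, and the swaps and splits of the arrays, were set before. The tests on Hprt were written after Hprt had been called, but before their own results were seen.

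The response of Plac8 to doxycycline differed between CD41-expressing and CD41- populations, by 4.09 on the log2 scale, in a test of the difference itself. Without doxycycline Plac8 was at 5.501 and 4.918 in CD41- cells of day 7 and day 8. It was at 2.969, 4.217 and 5.012 in untreated day 7 CD41+, day 8 CD41int and day 8 CD41hi cells. A higher starting level can make a log2 rise smaller, so part of the difference may come from the starting levels. That does not hold for day 8 CD41hi cells, which started no lower than day 8 CD41- cells. Which cells carried Plac8 in the CD41- populations was not tested. Myeloid cells, which carry Plac8, are a possible source of the rise. The myeloid list had a median of -0.106 over the 3 CD41-expressing pairs, and the highest of its 3 medians was -0.0303. These values go against a rise of myeloid genes as a group. The quartiles of the list lay on both sides of 0 in each of these pairs. A list median cannot show a small group of cells, so added myeloid cells stay open. A response set by the Meis2 level and not by the population stays open and cannot be told apart, because with doxycycline the lowest Meis2 level among CD41-expressing populations lay 0.213 log2 units above the highest among CD41- populations. Between day 7 CD41- and day 8 CD41int cells the rise of Meis2 ran the other way. It was 2.63 in the former, where Plac8 differed by 0.03, and 1.75 in the latter, where Plac8 differed by 3.69. The other pairs went with the Meis2 rise. It was 3.66 in day 7 CD41+ and 3.71 in day 8 CD41hi cells, where Plac8 differed by 4.40 and 4.47. In day 8 CD41- cells it was 1.46, where Plac8 differed by 0.17. A direct response to Meis2 in CD41-expressing cells is a further hypothesis and was not tested. The 10 splits of the 5 pairs into 3 and 2 are too few for a share under 0.05, with 1 gene in the real split, found by 1 split, and 0 as the highest other.

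The erythroid list had a lower response in CD41-expressing cells (camera adjusted p = 3.89e-05) and on day 8 (camera adjusted p = 0.0300), both by a test of the difference. The 2 tests are not separate findings. Each left the other grouping out of the response, and day 8 CD41int and CD41hi cells, with the lowest erythroid medians, counted in both. Both calls were lost with an estimated correlation (adjusted p = 0.731 and 0.843) and with fry (0.638 and 0.798), and that of day 8 also without the day 7 CD41-, day 8 CD41int or day 8 CD41hi pair (0.572, 0.3499 and 0.296). In CD41- cells the globins of the list were low (mean levels on day 7 of 1.92 for Hbb-bh1, 2.594 for Hbb-y and 2.989 for Hba-x), so a smaller fall there was in part fixed by their level. Over all pairs the 16 swaps within pairs are too few for a share under 0.05, with a camera p of 2.51e-12 for the real arrangement and 2.41e-09 for the smallest other. Fewer blood cells of every kind, or other cells thinning the sorted populations, could lower globins, and both stay open over the 3 CD41-expressing pairs. The lowest megakaryocyte median among them was 0.031, and the lower of the megakaryocyte and progenitor medians over these pairs was -0.0127. Yet members of the lists went both ways: in day 8 CD41hi cells the megakaryocyte median lay 0.700 above the erythroid one, with 0.928 between the quartiles of its members, and in day 7 CD41+ cells 0.345, with 0.505. In day 8 CD41int cells alone the distance was larger than that spread (0.609 against 0.472). Myeloid genes were lower beside the erythroid ones in day 8 CD41int (-0.2895, percentile 0.07) and CD41hi cells (-0.1991, percentile 0.53), as were endothelial genes in CD41hi cells (-0.4482, percentile 0). Added pluripotent, endodermal or stromal cells stay open too. In day 7 CD41+ cells all 3 medians were slightly below 0 (-0.068, -0.0275 and -0.007), at percentiles 36.19, 44.98 and 59.84 of random lists. The quartiles of each list lay on both sides of 0. Values so near those of random lists cannot decide for or against added cells there. In day 8 CD41hi cells all 3 medians were above 0 (0.102, 0.0532 and 0.0301, highest percentile 95.04). In day 8 CD41int cells pluripotency genes were at percentile 100 and endoderm genes at 61.84, and the endothelial median was 0.188, which leaves endothelial cells open as well. A smaller share of erythroid cells and a lower level of these genes per cell were not told apart by any test.

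Hprt rose with doxycycline in all 5 pairs. The A2lox system is known to place the inducible cassette upstream of Hprt on the X chromosome. A rise of the whole neighbourhood could have raised Hprt, but its 10 nearest tested genes had a median of -0.0547, and neither array scaling nor a purine programme is borne out, since 13 housekeeping genes had a median of -0.0439 and 15 purine genes of 0.0004. Transcripts running from the cassette into Hprt alone stay open, as does doxycycline itself, because no array came from treated cells without the transgene. The 16 swaps within pairs are too few for a share under 0.05, with 2 genes in the real arrangement, reached in 1, and 0 as the highest other.

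Pluripotency genes responded more positively on day 8 (camera adjusted p = 0.000125), a call lost with an estimated correlation (adjusted p = 0.843) and with fry (0.575). Their medians were -0.1956 and -0.068 in day 7 CD41- and CD41+ cells. On day 8 they were 0.1081, 0.3551 and 0.102 in CD41-, CD41int and CD41hi cells. The highest was that of CD41int cells, a population not sorted on day 7, so day and population cannot be told apart. The cardiac muscle list had a camera p of 2.48e-05 in the real arrangement and 0.000415 as the smallest other among the 16 swaps, too few for a share under 0.05. The 10 splits for the day are too few as well, with 0 genes in the real split, met by 10 of 10, and 1 as the highest other. Of 44 combinations of list and grouping, 5 had medians of opposite sign in every pair of the groups, where 2.75 were expected by chance. Besides pluripotency these were endoderm (a difference of mean medians of 0.0769), mast cell (-0.302) and stromal genes (0.0648) between days, with camera adjusted p for the difference of 0.708, 0.581 and 0.708, and megakaryocyte genes between CD41-expressing and CD41- cells (0.145, camera adjusted p = 0.325). No group held 4 or more arrays, so no array was tested as an outlier.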

How the results depend on the processing

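The test of all probes of the array was chosen after seeing the data, and the other alternatives before. The 2 genes called with doxycycline became 1 with the lower 50% of genes left out, with quantile normalization again, with trended robust variances, and with array weights, and that gene was Hprt. CD41-expressing populations alone gave 1 gene, Plac8, and neither of the 2 passed there (adjusted p = 0.112 for Meis2 and 0.182 for Hprt). With a mean per day 2 genes passed and 1 was shared, as Hprt lost its call (0.0949) and Plac8 passed (0.0131). A mean per day hides disagreement between populations. The count became 0 without the block, in CD41- populations alone and over all probes, and without each pair in turn it was 0 to 1. The erythroid and cardiac lists missed the threshold in CD41- populations alone (adjusted p = 0.129 and 0.426), with an estimated correlation (0.282 and 0.282) and with fry (0.228 and 0.140), and held without each pair (3.61e-12 to 3.86e-06, and 0.000134 to 0.00847). Counts without each array were 524 to 666 for day 7 CD41+ against CD41- and 918 to 1178 for day 8 CD41hi against CD41-. For CD41hi against CD41int they were 296 (without the doxycycline CD41int array) to 581 (without the untreated CD41hi array). Each of these counts left out 1 array, so the number of arrays cannot account for the spread between them. With all arrays the CD41hi against CD41int count was 775, and it rose to 1209 at a threshold of 0.1. A looser threshold can only add calls. The CD41 interaction gave 2 genes with trended robust variances, and day 8 CD41- cells 27 genes at 2-fold when the lower 50% of genes was left out. The causes of these changes were not tested.

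Signs turned, in values that had not passed, for Meis1 (-0.0288 to 0.197 without each pair), Pbx3 (-0.0872 to 0.0998, and -0.0878 in CD41-expressing populations) and Pbx4 (-0.189 to 0.0314, and 0.301 in CD41- populations). Lists that turned, with their adjusted p, were in CD41- populations alone the early response, endothelial, progenitor, stress response and pluripotency lists (0.760 each) and the myeloid list (0.719), and in CD41-expressing populations leukaemia (0.960) and megakaryocyte genes (0.524). Without the block endoderm (0.998), endothelial and progenitor genes (0.985 each) turned; with a mean per day progenitor (0.922), leukaemia (0.885) and megakaryocyte genes (0.976). Progenitor genes turned with mean probes (0.986) and fry (0.891), mast cell genes with no filter (0.952), and megakaryocyte genes with quantile normalization again (0.996). Ranges without each pair were 0.156 to 0.634 for endothelial, 0.449 to 0.942 for progenitor, 0.625 to 0.976 for leukaemia, 0.283 to 0.993 for mast cell, 0.501 to 0.996 for megakaryocyte, 0.156 to 0.942 for p53 and 0.0293 to 0.935 for pluripotency genes. Over the alternatives, 29 values of named genes (11 of Meis2, 9 of Hprt, the rest of Itga2b and Ptprc) and 53 of lists other than the erythroid and cardiac doxycycline lists missed the threshold, 6 and 2 passed it, and 997 and 647 kept direction and call. Signal over background limits what can be seen of Hbb-bh1 in day 7 CD41- cells, at 1.941 untreated and 1.900 with doxycycline where the first quartiles of those arrays were 1.879 and 1.895.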

Other observations

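The endothelial list was tested on these pairs only by its place among random lists. In day 8 CD41hi cells 7 of its 34 members were higher with doxycycline (median -0.45), whereas in day 8 CD41int cells 25 were higher (median 0.19); the difference between these populations was not tested. Cell cycle genes were at medians of 0.10 in day 7 CD41+ cells (percentile 99.95) and 0.11 in day 8 CD41hi cells (percentile 99.74), and at -0.08 in day 8 CD41int cells (percentile 3.03). Stox2, among the highest in day 7 CD41+ cells, was also at 2.44 in day 8 CD41hi cells.

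Of 15 retinoic acid response genes 4 fell and 1 rose in day 8 CD41hi against CD41- cells, and 2 fell and none rose in day 7 CD41+ against CD41- cells. On day 8 Crabp1, a retinoic acid binding protein, and Cyp26a1, which degrades retinoic acid, fell (-2.72 and -1.96), while Dhrs3, which reduces retinal, rose (2.16). The list as a whole did not pass (camera adjusted p = 0.282 on day 8 and 0.0597 on day 7). Cd34 rose in both contrasts with CD41- cells, by 3.71 on day 7 and 22.6-fold on day 8.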
